A study of Mus musculus with 8 samples.

How the data were processed

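The data are poly(A)-selected RNA-seq profiles of brown adipose tissue from mice of strain 129Sv/C57BL6j, aged 18 weeks, housed at 30 °C and fed chow. There were 8 libraries, 4 from wild-type mice (WT 55, 62, 64 and 65) and 4 from mice with an adipose tissue knockout of PGRMC2 (KO 53, 57, 70 and 71). Per the labels' protocols, libraries were made from 0.5 µg of total RNA with a stranded mRNA kit. The labels do not say whether each number is 1 animal, so p-values measure the spread between these samples. The numbers are not shared between groups, and no pairing or block was used.

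Per the submitters' processing notes, the genome build was mm10. The aligner, the counting tool, the annotation and the test behind the deposited comparison are not given in the sources used here. Per the file headers, the authors deposited 1 table with an FPKM value for each of 24535 gene symbols in each library. FPKM scales the fragments of a gene by its length and by the size of the library. Per the file headers, the authors also deposited a mean FPKM per group, a linear fold of those means and an adjusted p-value for KO against WT. The fold has no value in 7393 cells, where the WT mean is 0. The table lists no mitochondrially encoded gene, so that list is not analysed here. The authors' fold and p-value are described only as the authors' deposited table, and every other value was computed here from the per-library FPKM.

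Count tests need read counts, which FPKM values are not, so genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided) on log2(FPKM + 0.5). The 12235 genes with a mean of at least 0.5 FPKM over the 8 libraries were tested. P-values were adjusted by Benjamini-Hochberg over these genes, with a threshold of 0.05. A log2 change on this scale understates the change of genes with low values. The design, the 41 gene lists and the settings tried in place of each choice were fixed before the data were examined, except those stated as chosen later. The vesicle coat lists and the gene lengths used for shares of reads were chosen after the data were seen. Of the lists, 40 had at least 3 tested members and were tested with camera at a preset correlation of 0.01, adjusted over the lists. Camera was repeated with an estimated correlation, and fry was run on the same lists.

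The text names Pgrmc2 and Pgrmc1; the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 1 FPKM, no overlap between groups and a symbol not of the predicted-gene kind; and up to 4 members of each list with the smallest adjusted p. Of the list members so named, only some are described, and results of some genes are not reported here. Genes outside this rule were chosen after their values were seen, which is stated where they appear. Near-identical paralogs, such as the haemoglobin genes, are uncertain, since the authors' counting could split their reads.

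The FPKM sums differed between the groups, so the same test was run after median-of-ratios scaling, scaling to a common total, TPM scaling and quantile normalization. Median-of-ratios values are given beside the others because this scaling centres the median gene. Gene positions came from GENCODE M21 on GRCm38, the assembly that mm10 names, for the 23826 symbols (97.11%) with a gene of that name. The sum of FPKM times exon length was used to compare the share of reads in listed genes between groups. The absolute share depends on gene lengths that are not given in the sources used here. Exon lengths of the basic transcript set gave a WT mean of 73.8% and those of the full set gave 110.1%, which no share can reach. Only the ratio of KO to WT is therefore used, which was 1.079 with the basic lengths and 1.078 with the full lengths.

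Read totals are not given in the sources used here. Values of genes with few reads are multiples of the value of 1 read, and their ratios put the depth of the other 7 libraries at 1.30 to 1.43 times that of WT 55. No counting intervals are given, since absolute depth is unknown.

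The limma step was tested on simulated data with the means and residual spread of the 12235 genes and 200 changed genes. The noise was drawn independently for each gene and library, so genes did not move together as they do in the real libraries. The recovery and false calls below therefore need not hold for the real data. For KO against WT, 49.3% of genes changed by 0.5 on the log2 scale, 91.0% of those changed by 1 and 98.5% of those changed by 2 were recovered, and 5 unchanged genes were called. When every gene of the simulated KO libraries was also shifted by the observed median change, 675 unchanged genes were called without rescaling and 7 after median-of-ratios scaling. Positions, checks and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The alternatives tried were pseudocounts of 1 and 0.1, no filter or a minimum mean of 5 FPKM, the scalings above, limma without trend, robust, or with array weights, a skeletal muscle covariate, and leaving out each library in turn.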

Results

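Brown adipose tissue, the heat-producing fat of mammals, was profiled by poly(A) RNA-seq in 4 libraries from wild-type (WT) mice and 4 libraries from mice with an adipose tissue knockout (KO) of Pgrmc2, a membrane protein of the cytochrome b5-related progesterone receptor family. The series title describes this protein as a heme chaperone, and the comparison of KO with WT tissue asks which transcripts differ when it is lost. FPKM values summed to 289518 ± 1608 (SD, n = 4) per WT library and 310782 ± 3791 (SD, n = 4) per KO library, with no overlap (two-sided exact permutation p = 0.0286, the smallest that 70 assignments allow). Between 15542 and 16046 genes were above 0 in each library. The correlation of log2 values across genes, which are not independent replicates, was 0.964 to 0.983 between groups and 0.977 to 0.987 within them.

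The targeted gene was checked in every library first. Pgrmc2 (chromosome 3, 41066326 to 41083046, minus strand, GRCm38) was 35.5, 41.5, 40.4 and 36.8 FPKM in WT 55, 62, 64 and 65, and 3.23, 2.99, 3.67 and 3.07 FPKM in KO 53, 57, 70 and 71. The KO mean was 8.40% of the WT mean (log2 change -3.39, SE 0.08, limma adjusted p = 2.3e-08; two-sided exact permutation p = 0.0286). Its homologue Pgrmc1 was 52.1 ± 5.82 FPKM in WT and 55.7 ± 4.42 in KO (SD, n = 4; exact permutation p = 0.4).

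With the target among them, 15 genes passed the threshold with FPKM as deposited and under each of the 4 other scalings, 10 higher and 5 lower in KO. Apart from Pgrmc2 and those the naming rule takes, these genes were chosen after their values were seen. The higher genes were Kng1, Eif4a2, Cntfr, Fbxl5, Ptprs, Tex264, Pcbp4, Bhlhb9, Cd63 and Cma1. The other lower genes were Ptgds, Mecr, Spag5 and Cars2. Cntfr, a receptor subunit for ciliary neurotrophic factor, was 7.06 ± 2.47 FPKM in WT and 22.1 ± 3.41 in KO (SD, n = 4). Fbxl5, an iron-sensing ubiquitin ligase subunit, was 12.5 ± 1.20 FPKM in WT and 22.7 ± 0.760 in KO (log2 change 0.84, SE 0.08, limma adjusted p = 0.0027). The tetraspanin Cd63 was 16.9 ± 1.14 FPKM in WT and 27.6 ± 0.423 in KO. Ptgds, a prostaglandin D synthase, was 22.4 ± 5.48 FPKM in WT and 9.07 ± 0.656 in KO (log2 change -1.23, SE 0.15, limma adjusted p = 0.0092). Mecr, an enzyme of mitochondrial fatty acid synthesis, was 155.3 ± 10.3 FPKM in WT and 114.4 ± 2.03 in KO. Cars2, the mitochondrial cysteinyl-tRNA synthetase, was 9.92 ± 0.638 FPKM in WT and 7.11 ± 0.520 in KO.

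**Figure D1:**
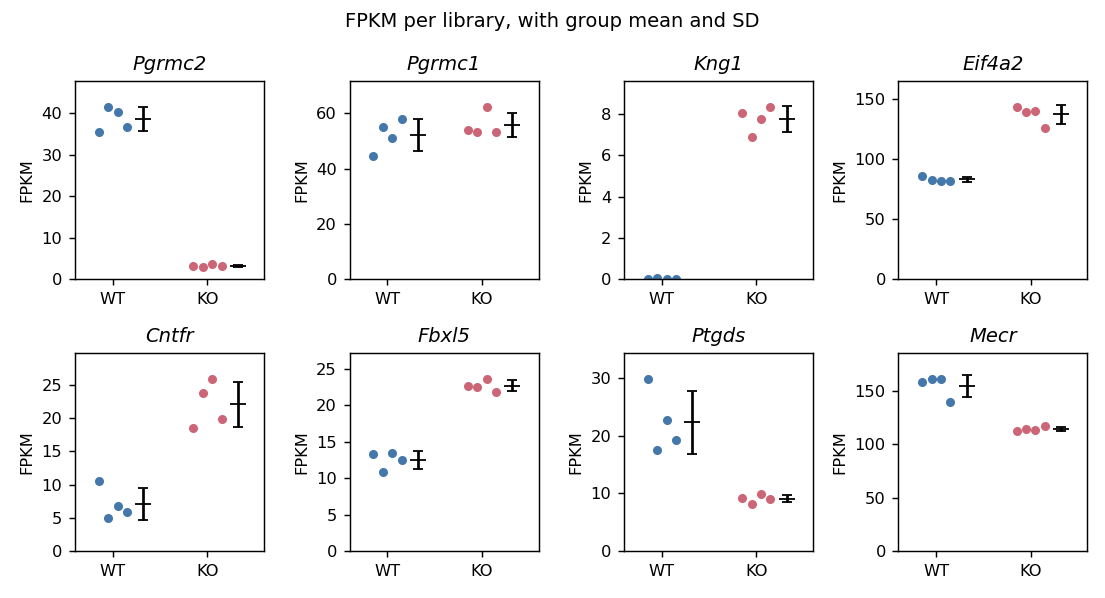
FPKM (vertical axes, from 0) of 8 genes in the 4 WT and 4 KO libraries, 1 point per library, with the group mean and SD at the right. For Kng1 in WT, which holds values of 0, no mean and SD are drawn. KO values of Pgrmc2 lie between 2.99 and 3.67 FPKM and WT values between 35.5 and 41.5 FPKM, while the groups overlap for Pgrmc1.

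With FPKM as deposited, limma called 1646 of 12235 genes, 1613 higher and 33 lower in KO, and 159 of them changed by at least 1 on the log2 scale. After median-of-ratios scaling it called 15 genes, 10 higher and 5 lower, so the share of higher calls went from 98.0% to 66.7%. The median log2 change of all genes was 0.17 with FPKM as deposited and -0.00 after this scaling, and the changes below are to be read against that shift. At an unadjusted p under 0.05 in limma, 4233 of the 12235 genes were higher and 170 lower with FPKM as deposited. After median-of-ratios scaling 1113 were higher and 1004 lower. The list counts below are to be read against these counts, since a list can hold many higher genes without exceeding the share among all genes. The groups did not overlap for 24.6% of tested genes with FPKM as deposited, where chance gives 2.86% for a single gene. A shift shared by many genes separates them together, so this share does not count independent changes. The share was not computed after rescaling. The count of called genes fell when any single library was left out, which also leaves fewer libraries to test. It was 24 without WT 64 and 24 without KO 53, 125 without KO 70 and 145 without WT 62. It was 628 without WT 65, 739 without KO 71, 1022 without KO 57 and 1468 without WT 55. The median log2 change of all genes stayed between 0.14 (without KO 70) and 0.19 (without WT 55) in these fits. After median-of-ratios scaling the count of called genes went from 3 (without KO 53 or without KO 71) over 5 (without WT 62, WT 64 or WT 65), 7 (without KO 57) and 8 (without KO 70) to 57 (without WT 55).

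Kng1 lies beside Adipoq on chromosome 16. Kng1 (23057865 to 23082078, plus strand) encodes kininogen 1. It was listed at 0 in 3 WT libraries and at 0.038 FPKM in WT 62, and at 8.05, 6.92, 7.78 and 8.36 FPKM in KO 53, 57, 70 and 71. Eif4a2 (23107444 to 23114136, plus strand), a translation initiation helicase, rose from 83.1 ± 1.96 to 137.1 ± 7.79 FPKM (SD, n = 4; limma adjusted p = 0.0017). The next gene, Rfc4 (23113943 to 23127737, minus strand), which overlaps Eif4a2 at its end and was chosen after its values were seen, rose from 5.10 to 8.28 FPKM (limma adjusted p = 0.018), but not after median-of-ratios scaling (limma adjusted p = 0.132). The adipokine gene Adipoq was 995.7 FPKM in WT and 1157 FPKM in KO (limma adjusted p = 0.175). The paralog Kng2 was 109.7 FPKM in WT and 108.2 FPKM in KO.

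**Figure D2:**
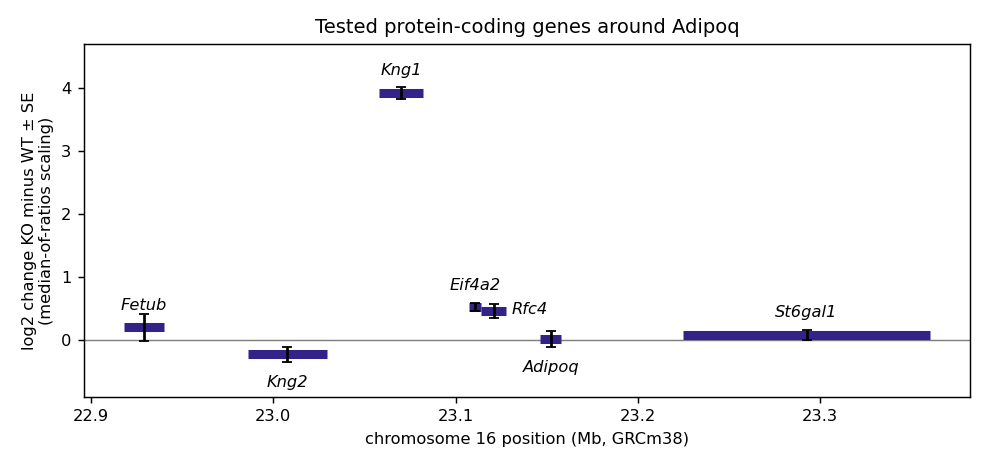
Log2 change of KO minus WT with its SE after median-of-ratios scaling (vertical axis) for the tested protein-coding genes around Adipoq, drawn at their chromosome 16 positions in Mb (horizontal axis, bar length to scale). Kng1, Eif4a2 and Rfc4 stand above 0, while Adipoq is 0.02 from it.

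Skeletal muscle genes made up most of the other large rises. Of 24 skeletal muscle markers, 21 rose, 0 fell and 3 did not pass; 24 rose when adjusted over the list alone, and after median-of-ratios scaling 0 passed over all genes and 24 over the list alone. Their median log2 change was 1.75. The fast myosin gene Myh2 rose from 2.01 ± 0.572 to 12.4 ± 7.67 FPKM, the calcium pump gene Atp2a1 from 49.3 ± 24.3 to 206.7 ± 109.9 FPKM, and the muscle actin gene Acta1 from 97.3 ± 42.8 to 392.8 ± 274.3 FPKM (SD, n = 4). Actn3, Myh4, Myoz2, Mybpc1 and Ckm were also among the 10 largest rises, as was the microRNA gene Mir568, listed at 0 in 2 WT libraries. KO 71 had the highest values of these 8 muscle genes (Acta1 802.0 FPKM against 218.9 to 288.9 in the other KO libraries). The camera test of the list gave an adjusted p = 1.1e-08, and an adjusted p = 0.480 with an estimated correlation. With the muscle level as a covariate, 2 genes stayed past the threshold, Pgrmc2 and Kng1. The median log2 change of all genes was then 0.17, as without it, while the SE of the difference of library medians went from 0.04 to 0.09, and the muscle level was higher in every KO library than in every WT library.

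**Figure D3:**
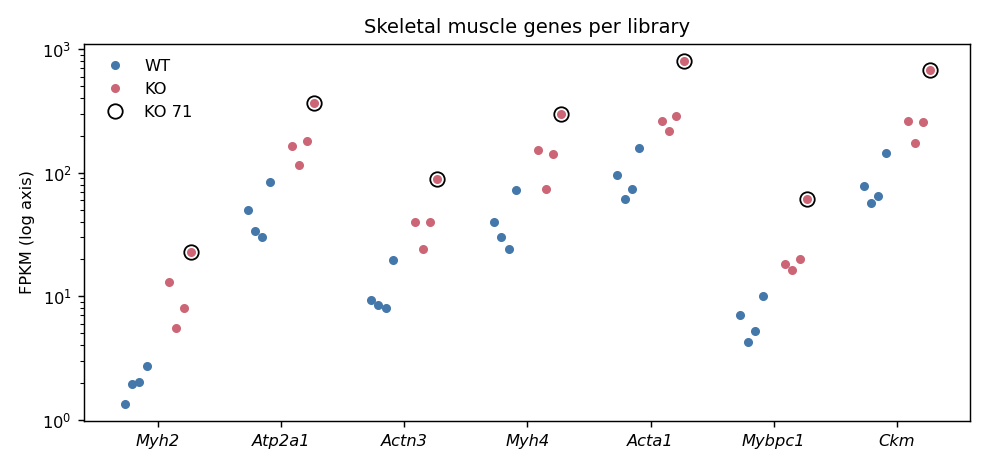
FPKM of 7 skeletal muscle genes (log vertical axis), 1 point per library, with KO 71 circled. For each gene the 4 KO points lie above the 4 WT points, and KO 71 is highest, for example 677.3 FPKM of Ckm.

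Gbp2b had the largest fall after Pgrmc2. This interferon-induced GTPase gene was 9.39 to 20.2 FPKM in WT, and 0, 0.099, 4.35 and 4.13 FPKM in KO 53, 57, 70 and 71. The authors' deposited table gives it an adjusted p of 0.456, from a test that is not named there. The chemokine genes Cxcl9 (17.3 ± 9.77 to 6.58 ± 0.470 FPKM) and Ccl2 (1.93 ± 0.966 to 0.553 ± 0.233 FPKM) fell, as did the leukocyte gene Cd52, Ubd, Prr32, Ctcflos and Spag5 (SD, n = 4). Of the genes in this paragraph, Spag5 alone passed after median-of-ratios scaling. Limma called 0 of 21 interferon response genes (0 higher and 2 lower at an unadjusted p under 0.05, 0 and 7 after median-of-ratios scaling), and the list ranked below other genes (camera adjusted p = 1.0e-12; adjusted p = 0.405 with an estimated correlation). Cxcl10 was 13.6, 3.08, 1.25 and 5.78 FPKM in WT 55, 62, 64 and 65, and 0.641 to 1.09 FPKM in KO. Limma called 0 of 11 lymphocyte markers (0 higher and 2 lower unadjusted, 0 and 5 after median-of-ratios scaling; camera adjusted p = 4.3e-10, lower; adjusted p = 0.405 with an estimated correlation). Cd3d was 1.05 ± 0.838 FPKM in WT and 0.257 ± 0.189 in KO. WT 55 and WT 65 had the 2 highest values of Cxcl9, Cd52, Ccl2, Cd3d and Cd4. Of 23 macrophage markers 1 fell, Ccl2, and 22 did not pass (3 higher and 1 lower unadjusted, 0 and 5 after median-of-ratios scaling; camera adjusted p = 4.3e-06, lower; adjusted p = 0.500 with an estimated correlation). The 3 higher unadjusted were Cd163 (0.858 ± 0.253 FPKM in WT and 1.41 ± 0.344 in KO), Trem2 (2.61 ± 0.220 and 3.50 ± 0.668 FPKM) and Mrc1 (2.96 ± 0.558 and 4.34 ± 1.11 FPKM). None of 10 erythroid markers passed (1 higher and 3 lower unadjusted, 0 and 7 after median-of-ratios scaling; camera adjusted p = 3.9e-08, lower; adjusted p = 0.405 with an estimated correlation). None of 6 proliferation genes passed (0 unadjusted, 0 higher and 1 lower after median-of-ratios scaling; camera adjusted p = 0.0010, lower; adjusted p = 0.405 with an estimated correlation). None of 14 immediate early genes passed (0 higher and 2 lower unadjusted, 0 and 5 after median-of-ratios scaling; camera adjusted p = 0.00024, lower; adjusted p = 0.405 with an estimated correlation).

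Of 21 tricarboxylic acid cycle enzymes, 2 fell, 0 rose and 19 did not pass. Adjusted over the list alone 2 fell, and 16 did so after median-of-ratios scaling, where 21 lay below 0. Unadjusted, 0 were higher and 5 lower, and 0 and 16 after this scaling. Fumarase Fh1 fell from 374.4 ± 34.6 to 294.0 ± 21.4 FPKM and Idh3g, an isocitrate dehydrogenase subunit, from 732.3 ± 46.6 to 610.8 ± 14.4 FPKM (SD, n = 4). The list ranked below other genes (camera adjusted p = 1.9e-12; adjusted p = 0.405 with an estimated correlation). Among 37 complex I subunits 1 fell, Ndufv1 (585.0 ± 44.6 to 475.5 ± 18.3 FPKM), and 36 did not pass (camera adjusted p = 7.1e-06, lower; adjusted p = 0.530 with an estimated correlation). At an unadjusted p under 0.05, 1 of them was higher and 2 were lower, and after median-of-ratios scaling 0 were higher and 11 lower, with 37 of 37 below 0. Subunits that move together are not separate evidence. Their mean log2 level after this scaling overlapped between groups (7.928 in WT 65, 7.938 in KO 57 and 7.933 in KO 71) and was lowest in KO 70 (7.622). Of the 35 ways to split the libraries into groups of 4, 7 gave as small a camera p for complex I after this scaling, and 4 did for the tricarboxylic acid cycle, the real split included. Limma called 0 of 4 complex II subunits (0 higher and 1 lower unadjusted, 0 and 2 after median-of-ratios scaling; camera adjusted p = 0.0053, lower; adjusted p = 0.405 with an estimated correlation). It called 0 of 9 complex III subunits (0 higher and 1 lower unadjusted, 0 and 5 after median-of-ratios scaling; camera adjusted p = 0.00016, lower; adjusted p = 0.418 with an estimated correlation). In complex IV 1 of 15 subunits rose, the muscle form Cox6a2 (2 higher and 0 lower unadjusted, 1 and 2 after median-of-ratios scaling; camera adjusted p = 0.128, lower). In ATP synthase 1 of 14 rose, Atp5j (2 higher and 0 lower unadjusted, 0 and 3 after median-of-ratios scaling; camera adjusted p = 0.0528, lower). Of 78 mitochondrial ribosomal proteins 1 rose, Mrps35 (9 higher and 0 lower unadjusted, 0 and 9 after median-of-ratios scaling; camera adjusted p = 0.201, lower). Of 29 biogenesis, import and dynamics genes 2 rose, Mfn1 and Bnip3 (8 higher and 0 lower unadjusted, 0 and 2 after median-of-ratios scaling; camera adjusted p = 0.855). Of 14 mitochondrial chaperones and proteases 3 rose, Yme1l1, Hspe1 and Clpx (5 higher and 1 lower unadjusted, 0 and 6 after median-of-ratios scaling; camera adjusted p = 0.488, lower). So the balance of unadjusted counts turned with the scaling for complex IV, ATP synthase, mitochondrial ribosomal proteins, biogenesis genes and chaperones. None of the genes named in this paragraph passed over all genes after median-of-ratios scaling, where 12 of 14 ATP synthase subunits, 66 of 78 mitochondrial ribosomal proteins, 22 of 29 biogenesis genes and 10 of 14 chaperones and proteases lay below 0.

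Among heme and iron genes few passed. Of 15 heme synthesis genes 2 rose, ferrochelatase Fech (36.6 ± 1.96 to 43.5 ± 1.53 FPKM) and Clpx, and 13 did not pass (4 higher and 0 lower unadjusted, 0 and 1 after median-of-ratios scaling; camera adjusted p = 0.883). The log2 change of Fech was 0.05 after this scaling. Limma called 0 of 13 heme degradation and transport genes (2 higher and 2 lower unadjusted, 0 and 2 after median-of-ratios scaling; camera adjusted p = 0.0687). It called 0 of 11 genes of the membrane-associated progesterone receptor and cytochrome b5 family (1 higher and 1 lower unadjusted; camera adjusted p = 0.0513). In this family 0 genes were higher and 4 lower unadjusted after median-of-ratios scaling, where 10 of 11 lay below 0 and 4 fell adjusted over the list alone. It called 0 of 27 BACH1 and NRF2 targets (4 higher and 1 lower unadjusted), while the list ranked below other genes (camera adjusted p = 0.0022; adjusted p = 0.459 with an estimated correlation). Of these targets 0 were higher and 6 lower unadjusted after median-of-ratios scaling, where 20 lay below 0 and 7 above. Of 22 iron handling genes 4 rose, Steap3 (5.34 ± 0.720 to 7.94 ± 0.861 FPKM), Aco1, Heph and Slc25a28 (6 higher and 0 lower unadjusted, 3 and 3 after median-of-ratios scaling, where 13 lay below 0; camera adjusted p = 0.855). Of 17 cytochrome P450 genes 3 rose, Cyp2e1 (31.4 ± 14.4 to 110.4 ± 44.6 FPKM), Cyp2f2 and Cyp2j6 (5 higher and 0 lower unadjusted, 3 and 2 after median-of-ratios scaling; camera adjusted p = 0.826). None of the genes named in this paragraph passed over all genes after median-of-ratios scaling.

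Of 30 thermogenic and brown adipocyte genes 3 rose and 27 did not pass (11 higher and 2 lower unadjusted, 3 and 5 after median-of-ratios scaling; camera adjusted p = 0.201). Pdk4, an inhibitor of pyruvate oxidation, rose from 271.8 ± 37.8 to 508.1 ± 104.9 FPKM, Ucp3 from 10.9 ± 2.32 to 15.6 ± 1.19 FPKM and the potassium channel gene Kcnk3 from 66.7 ± 6.66 to 84.3 ± 7.26 FPKM (SD, n = 4). Of 18 lipolysis and lipid droplet genes 5 rose, among them the lipase activator Abhd5 (17.0 ± 0.967 to 24.5 ± 1.11 FPKM), Mgll and Fitm2 (9 higher and 0 lower unadjusted, 4 and 1 after median-of-ratios scaling; camera adjusted p = 0.267). Of 30 fatty acid oxidation genes 5 rose, among them Acaa1b (3.22 ± 0.437 to 5.48 ± 0.570 FPKM) and Acad10 (8 higher and 1 lower unadjusted, 2 and 2 after median-of-ratios scaling; camera adjusted p = 0.826). Of 20 general adipocyte markers 2 rose, Lpl and Cd36 (5 higher and 1 lower unadjusted, 0 and 3 after median-of-ratios scaling; camera adjusted p = 0.128). Of 26 fatty acid and triglyceride synthesis genes 2 rose, Acacb and Agpat3 (4 higher and 1 lower unadjusted, 1 and 5 after median-of-ratios scaling), while the list ranked below other genes (camera adjusted p = 0.00024; adjusted p = 0.418 with an estimated correlation). The 23 cholesterol synthesis genes ranked below other genes as a list (3 higher and 0 lower unadjusted, 1 and 5 after median-of-ratios scaling; camera adjusted p = 0.0012; adjusted p = 0.530 with an estimated correlation). Of 14 white adipocyte-enriched genes 2 rose, Agt and Ctsz (4 higher and 3 lower unadjusted, 2 and 5 after median-of-ratios scaling), while the list ranked below other genes (camera adjusted p = 0.0186; adjusted p = 0.418 with an estimated correlation). Of 25 glucose uptake, glycolysis and insulin signalling genes 3 rose and 2 fell (8 higher and 5 lower unadjusted, 2 and 7 after median-of-ratios scaling; camera adjusted p = 0.0238, lower; adjusted p = 0.405 with an estimated correlation). Pfkm, the muscle form of phosphofructokinase, rose from 57.6 ± 8.27 to 97.8 ± 22.2 FPKM and Pfkp fell from 20.4 ± 3.38 to 15.4 ± 0.722 FPKM. None of the genes in this paragraph passed in limma over all genes after median-of-ratios scaling.

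Of 8 neutrophil and mast cell markers 4 rose, all of them mast cell protease genes: Cma1 (1.10 ± 0.117 to 2.69 ± 0.262 FPKM), Mcpt4 (2.29 ± 0.599 to 5.31 ± 0.908 FPKM), Cpa3 and Tpsb2 (4 higher and 0 lower unadjusted under both scalings; camera adjusted p = 0.0991). Adjusted over the list alone 4 passed, also after median-of-ratios scaling. Of 8 Schwann and nerve markers 3 rose, among them Mbp (6.91 ± 1.05 to 9.86 ± 1.22 FPKM) and Pmp22 (3 higher and 0 lower unadjusted under both scalings; camera adjusted p = 0.128). Of 15 adipose progenitor and fibroblast markers 2 rose, Igfbp6 and Dcn (5 higher and 0 lower unadjusted, 2 and 0 after median-of-ratios scaling; camera adjusted p = 0.272). Of 16 endothelial markers 1 rose, Emcn, of 12 smooth muscle and pericyte markers 2 rose, Abcc9 and Des, and of 25 matrix and fibrosis genes 1 rose, Fn1 (camera adjusted p = 0.826 for each list). Unadjusted, these 3 lists had 2, 5 and 8 higher and 0 lower, and after median-of-ratios scaling 0, 2 and 1 higher and 0, 2 and 0 lower. Of the genes named in this paragraph, Cma1 alone passed over all genes after that scaling. Des is also abundant in skeletal muscle.

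Of 22 integrated stress response genes 5 rose, among them Aldh1l2 (0.423 ± 0.189 to 1.70 ± 0.833 FPKM) and Phgdh (5 higher and 1 lower unadjusted, 2 and 2 after median-of-ratios scaling; camera adjusted p = 0.128). Limma called 0 of 20 endoplasmic reticulum stress and chaperone genes (3 higher unadjusted; camera adjusted p = 0.513), and after median-of-ratios scaling 0 were higher and 4 lower unadjusted, with 16 of 20 below 0. Of 66 cytosolic ribosomal proteins 8 rose, among them Rps21 and the muscle form Rpl3l (26 higher and 2 lower unadjusted, 3 and 2 after median-of-ratios scaling, where 36 lay below 0; camera adjusted p = 0.547). Of 20 circadian clock and REV-ERB target genes 1 rose, Rora (3 higher and 0 lower unadjusted, 1 and 0 after median-of-ratios scaling; camera adjusted p = 0.412). None of the genes named in this paragraph passed over all genes after median-of-ratios scaling.

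Adjusted over the list alone, counts differed from those over all genes for 16 lists. They were 24 rose for skeletal muscle, 8 rose and 4 fell for glucose uptake and glycolysis, 3 rose and 3 fell for white adipocyte-enriched genes, 5 rose for smooth muscle, 4 rose for cytochrome P450, 7 rose for cytosolic ribosomal proteins, 3 rose for heme synthesis and 3 for progenitors. They were 1 fell for complex II, and 0 for complex I, mitochondrial ribosomal proteins, clock genes, fatty acid synthesis, general adipocyte markers, matrix genes and endothelial markers. In the other 24 lists they were the same. After median-of-ratios scaling the counts over the list alone were 24 rose for skeletal muscle, 16 fell for the tricarboxylic acid cycle, 7 fell for erythroid markers, 4 rose for neutrophil and mast cell markers, 4 fell for the progesterone receptor family and 3 fell for immediate early genes. They were 1 rose and 5 fell for glucose uptake and glycolysis, 2 rose and 4 fell for white adipocyte-enriched genes, 1 rose and 1 fell for thermogenic genes, 2 rose for cytochrome P450 and for integrated stress response genes, and 2 fell for complex II and for heme degradation. They were 1 rose for fatty acid oxidation, lipolysis and Schwann markers, 1 fell for complex I, macrophage markers and mitochondrial chaperones, and 0 for the lists not named in these sentences. Camera called 16 of 40 lists (20 unadjusted), 0 with an estimated correlation (3 unadjusted), and fry called 8. After median-of-ratios scaling camera called 22 lists: those of white adipocyte-enriched genes (adjusted p = 0.199) and glycolysis (adjusted p = 0.0573) ended. Added were ATP synthase (adjusted p = 0.0125), mitochondrial ribosomal proteins (adjusted p = 3.5e-05), the progesterone receptor family (adjusted p = 0.0186), endoplasmic reticulum stress (adjusted p = 0.0400) and mitochondrial chaperones (adjusted p = 0.0158), all lower. Also added were mast cell (adjusted p = 0.00197), progenitor (adjusted p = 0.0158) and Schwann markers (adjusted p = 0.0111), all higher. The estimated correlation was not run after this scaling. Camera compares a list with all other genes, so a list could have a median above 0 and rank lower, as for complex I (median log2 change 0.01, mean -0.00). Median and mean also differed in sign for fatty acid synthesis, cholesterol synthesis, immediate early genes and the progesterone receptor family. Against the median of all genes, the thermogenic and matrix lists had a higher median and a lower camera rank, and the heme synthesis and biogenesis lists a lower median and a higher camera rank.

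The authors' deposited table gives 550 genes with an adjusted p below 0.05, 314 higher and 236 lower in KO. In the authors' deposited table the fold of Pgrmc2 is 0.0840. Of 519 genes so called in the authors' deposited table and tested here, 311 were also called by limma with FPKM as deposited and 15 after median-of-ratios scaling. The sign was the same for 519 and 513 of them. With FPKM as deposited, 280 higher and 31 lower calls were shared with the authors' deposited table, where lists drawn independently would share 39.2 and 0.599. Both come from the same libraries.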

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

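The tests of the broad rise, of the Kng1 segment and of the muscle genes were chosen after the results were seen, while the counts over other splits of the libraries were planned.

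Most genes were higher in KO with FPKM as deposited: the library medians of log2 values differed by 0.19 (SE 0.04; 95% interval 0.08 to 0.30). A larger share of reads in the listed genes may account for it, and at an equal share the difference was 0.0881 (SE 0.0400, 95% interval -0.01 to 0.19), with 27 genes called. That share was computed from the same FPKM values. A broad rise from any cause therefore raises it, and dividing by it lowers the difference by arithmetic. The value at an equal share thus cannot tell this explanation from others. Skeletal muscle RNA might also add to the broad rise, and with the muscle level as a covariate the difference was 0.17 (SE 0.09, 95% interval -0.04 to 0.39). A first bound of 2 SE would have excluded both explanations, at 2.20 and 2.05 SE, and was replaced by the 95% interval after the result was seen because so few libraries need a wider bound. Both therefore stay open beside an effect of the genotype, and the gene lengths behind the authors' FPKM are not given in the sources used here. FPKM is relative to the size of each library, so a shift of the median gene does not show that most transcripts rose. Of the genes called in the authors' deposited table, 314 were higher and 236 lower in KO.

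Kng1, Eif4a2 and Rfc4 are neighbours on chromosome 16 beside Adipoq, and all 3 were higher in every KO library than in every WT library. Chance was not excluded by a scan of t values taken after median-of-ratios scaling. In 2.26% of 10000 shuffles of protein-coding genes over positions any run of 3 reached as high a smallest t (4.09, next run 3.48). The run length and the statistic, however, were set after the 3 genes were seen. The run also leaves out the snoRNA genes Snord2 and Snora81, which lie inside Eif4a2. Extra copies of the segment, such as those an Adipoq-driven transgene could carry, may raise them: the log2 changes of Eif4a2 and Rfc4 after median-of-ratios scaling differed by 0.0608 (SE 0.122), a weak test, and the labels name no transgene. Copies expressed at the WT level would not account for Kng1, listed at 0 in 3 WT libraries. Whether added copies were expressed otherwise was not tested. Strain variants linked to the region were not excluded. After median-of-ratios scaling, 13.3% of 135 other protein-coding genes within 10 Mb passed an unadjusted p of 0.05. Elsewhere 17.4% did (Fisher's exact p = 0.253, odds ratio 0.729, 95% interval 0.417 to 1.21).

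The 24 skeletal muscle markers were higher in KO, and KO 71 had the highest level. Within the groups their mean pairwise correlation over libraries was 0.882, above all of 10000 random lists of like expression (95th percentile 0.134). Varying amounts of muscle carried over in dissection may give this. Genes regulated together would also exceed random lists, so the test cannot tell carry-over from an effect of the genotype. Acta1 reached 802.0 FPKM and Ckm 677.3 FPKM in KO 71. All KO libraries lay above all WT libraries, so an effect of the genotype on muscle genes stays open and was not tested.

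The libraries can be split into groups of 4 in 35 ways. The real split gave the most called genes (1646, highest other 2), higher genes (1613, highest other 2), lower genes (33, highest other 2), changes of at least 1 (159, highest other 2) and called genes after median-of-ratios scaling (15, highest other 5). For the other splits the counts set beside higher genes and lower genes are those of the direction with more calls. In each case the real split was 1 of 35 splits with as many, which argues against chance assignment of the libraries. This is the smallest share these splits allow, and the counts overlap, so they are not separate evidence. The counts also depend on which libraries are kept: 24 genes were called without WT 64 or KO 53, and after median-of-ratios scaling 3 without KO 53 or KO 71. For gene lists chance cannot be excluded: 19 of the 35 splits called as many as the 16 of the real split (highest other 24). None of the 40 lists fixed beforehand had its smallest camera p in the real split.

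Single libraries stood apart in 20 of 238 groups of 4, where chance alone gives about 1 in 20 groups, or 11.9. The value is the gap of the extreme library to its nearest neighbour as a share of the group's range. It was 0.888 for Pgrmc1 in KO 70, 0.847 for Mecr in WT 65 and 0.833 for Actn3 in WT 65. It was 1 by construction for Kng1 in WT 62, at 0.038 FPKM beside WT values of 0. It was 0.844 for Mybpc1 in KO 71, 0.946 for Idh3g in WT 65, 0.898 for Mgll in WT 64 and 0.931 for both Acad10 in WT 55 and Cxcl10 in KO 53. It was 0.868 for Pmp22 in KO 70, 0.869 for Mbp in WT 62, 0.848 for Dcn in WT 65, 0.88 for Pfkm in KO 71 and 0.961 for Adipoq in KO 57. Among mean list levels after median-of-ratios scaling it was 0.866 for complex I and 0.851 for the tricarboxylic acid cycle, both in KO 70, and 0.988 for complex IV in WT 64. It was 0.872 for proliferation genes in KO 53, 0.857 for skeletal muscle markers in KO 71 and 0.831 for erythroid markers in WT 55.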

How the results depend on the processing

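Leaving out both WT 55 and KO 71, the covariate joined to median-of-ratios scaling, and all alternatives to the count after median-of-ratios scaling were chosen after the data were seen. Called genes numbered 1646 (1613 higher, 33 lower, 159 changed by at least 1) with FPKM as deposited. They numbered 15 (10 higher, 5 lower, 4 of that size) with median-of-ratios scaling, 28 (22, 6 and 5) with a common total, 31 (25, 6 and 10) with TPM scaling and 18 (12, 6 and 4) with quantile normalization. Each of these scalings moves the median gene towards 0, and all genes they called were among the 1646. Without a filter the count was 713 (700 higher, 13 lower, 46 of that size), and limma without trend gave 992 (973 higher, 19 lower). A minimum mean of 5 FPKM left 77 genes of that size. With the muscle covariate, and with it joined to median-of-ratios scaling, 2 genes were called (1 higher, 1 lower, 2 of that size). Without WT 55 and KO 71 there were 837 (799 higher) and 26 lists. With each library left out the count ranged from 24 (without WT 64 or KO 53) to 1468 (without WT 55), higher genes from 21 (without WT 64) to 1403 (without WT 55), lower genes from 2 (without KO 53) to 65 (without WT 55) and changes of at least 1 from 6 (without KO 53) to 179 (without KO 57). The count after median-of-ratios scaling was 6 without trend, 8 without a filter, 2 with the covariate, and 3 (without KO 53 or KO 71) to 57 (without WT 55) with each library left out. The planned rescaling without mitochondrially encoded genes was not run apart, since with none listed it equals the common total. No paired analysis was possible because the groups share no replicate numbers. Pgrmc2 and Kng1 were called under all scalings and the covariate. The cause of the other changes was not tested.

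Camera called 16 lists, 0 with an estimated correlation, and fry called 8. Fry was run only with FPKM as deposited, where the median log2 change of all genes was 0.17. All 8 lists it called were higher, and the test does not separate them from that shift. Fry, which asks whether a list moves on balance one way and compares it with no other genes, ended all 16 calls of camera. It ended the list calls of complex II 0.345, complex III 0.598, tricarboxylic acid cycle 0.243, interferon response 0.488, proliferation 0.522, immediate early 0.788, macrophage 0.875, lymphocyte 0.267, skeletal muscle 0.0513 and erythroid 0.332, and also ended, with the opposite sign and short of the threshold, those of complex I 0.908, BACH1 and NRF2 targets 0.598, fatty acid synthesis 0.816, cholesterol synthesis 0.788, white adipocyte-enriched 0.335 and glycolysis 0.176, and added those of cytosolic ribosomal proteins 0.0142, biogenesis and heme synthesis 0.0402, iron handling 0.0114, lipolysis 0.00669 and mast cells 0.00265, and called, with a sign opposite to that of camera as reported, thermogenic 0.00133 and mitochondrial chaperones 0.0443. An estimated correlation ended the list calls of complex I and cholesterol synthesis 0.530, complex II, tricarboxylic acid cycle, glycolysis, interferon response, proliferation, immediate early, lymphocyte, erythroid 0.405, complex III, fatty acid synthesis, white adipocyte-enriched 0.418, BACH1 and NRF2 targets 0.459, macrophage 0.500 and skeletal muscle 0.480. Testing without a filter ended the list calls of complex II 0.0526, white adipocyte-enriched 0.231 and glycolysis 0.301. Quantile normalization ended the list calls of complex II 0.142, complex III 0.0965, fatty acid synthesis 0.226 and white adipocyte-enriched and glycolysis 0.261, and added those of mitochondrial ribosomal proteins 6.5e-04, lipolysis 0.0202, mast cells 0.00437 and progenitors and Schwann and nerve 0.0173. The skeletal muscle covariate ended the list calls of complex II 0.0860, BACH1 and NRF2 targets 0.496, white adipocyte-enriched 0.708 and glycolysis 0.0640, and added those of mitochondrial ribosomal proteins 0.0364, clock 0.0148, mast cells 0.00704, progenitors 0.0147 and Schwann and nerve 0.00393, and called, with a sign opposite to that of camera as reported, matrix 0.00704. TPM scaling ended the list calls of white adipocyte-enriched 0.0606, and added those of complex IV and progesterone receptor family 0.0218, ATP synthase 0.00279, mitochondrial ribosomal proteins 0.00101, mast cells 0.0116 and Schwann and nerve 0.0277. Scaling to a common total ended the list calls of white adipocyte-enriched 0.0624, and added those of complex IV and progesterone receptor family 0.0225, ATP synthase 0.00300, mitochondrial ribosomal proteins 0.00101, mast cells 0.0105 and Schwann and nerve 0.0274. A minimum mean of 5 FPKM added those of ATP synthase 0.0119, mitochondrial ribosomal proteins and heme degradation 0.0210, progesterone receptor family 0.0143 and general adipocyte 0.0238. Median-of-ratios scaling ended the list calls of white adipocyte-enriched 0.199 and glycolysis 0.0573, and added those of ATP synthase 0.0125, mitochondrial ribosomal proteins 3.5e-05, progesterone receptor family 0.0186, endoplasmic reticulum stress 0.0400, mitochondrial chaperones and progenitors 0.0158, mast cells 0.00197 and Schwann and nerve 0.0111. Limma without trend added those of ATP synthase 0.0380 and progesterone receptor family 0.0400. A pseudocount of 0.1 added those of progesterone receptor family 0.0494. Limma with array weights ended the list calls of glycolysis 0.0546, and added those of progesterone receptor family 0.0262.

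With each library left out in turn, the adjusted camera p ranged for complex I 1.4e-09 (without WT 65) to 0.0687 (without KO 70), complex II 5.9e-04 (without WT 65) to 0.0774 (without KO 70), complex IV 0.0398 (without WT 65) to 0.757 (without KO 70) and ATP synthase 0.00183 (without KO 71) to 0.598 (without KO 70). It ranged for mitochondrial ribosomal proteins 0.00549 (without KO 57) to 0.535 (without WT 64), heme degradation 0.0226 (without KO 71) to 0.300 (without KO 70), progesterone receptor family 0.00253 (without WT 55) to 0.156 (without WT 62) and BACH1 and NRF2 targets 1.2e-04 (without WT 55) to 0.155 (without WT 62). The ranges were, for fatty acid synthesis 6.6e-08 (without WT 55) to 0.0864 (without WT 62), cholesterol synthesis 2.9e-05 (without WT 64) to 0.0866 (without WT 62), general adipocyte 0.00921 (without WT 55) to 0.532 (without WT 64) and white adipocyte-enriched 0.00320 (without KO 70) to 0.109 (without WT 64). Further ranges were, for glycolysis 0.00383 (without WT 65) to 0.195 (without WT 62), integrated stress response 0.0113 (without WT 55) to 0.830 (without WT 62), mast cells 0.0398 (without WT 65) to 0.196 (without WT 55) and progenitors 0.0274 (without KO 57) to 0.611 (without KO 53). The last range was, for Schwann and nerve 0.0273 (without WT 62) to 0.303 (without WT 65). With the muscle covariate the log2 changes of 3 genes turned, to -0.203 for Cox6a2, -0.0145 for Des and -0.0246 for Myoz2. Depth relative to WT 55 was 1.30 to 1.43 in the other libraries, and absolute depth is unknown.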

Other observations

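Genes of the vesicle coats that carry proteins between the endoplasmic reticulum and the Golgi were examined with lists and a test chosen after the table of all genes was seen. The COPI and COPII lists hold coat subunits and associated genes that are not subunits, such as Sec16a, Sec16b, Sec22b and Preb. After median-of-ratios scaling, 22 of 23 genes on these lists lay above 0, with a median log2 change of 0.25. In limma 0 of them passed and 16 had an unadjusted p under 0.05. As a joint list they had a camera p of 0.00492 with an estimated correlation, the smallest of the 35 splits (lowest other 0.0954). The lists were picked from these data with the real split known, so neither value can test the pattern. A joint rise of the genes on these lists may be a hypothesis for other samples, and it stays open here. The TMED cargo receptors of the same pathway, as a list, gave a limma camera p of 0.486.

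Around Pgrmc2 itself, 14.6% of 41 protein-coding genes within 10 Mb passed an unadjusted p of 0.05 after median-of-ratios scaling. Elsewhere 17.4% did (Fisher's exact p = 0.836).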
